A study of Tribolium castaneum with 48 samples.

How the data were processed

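Messenger RNA was measured by sequencing in whole larvae of the red flour beetle Tribolium castaneum. The mothers of the larvae had either been pricked with heat-killed Bacillus thuringiensis, called primed here, or had not, called unprimed. Larvae were taken uninfected at 0 h, or at 2, 6, 8 or 12 h after infection with the same bacterium at a dose the labels call LD50. It was run as 2 separate experiments, called experiment 1 (0, 2, 6 and 12 h) and experiment 2 (0, 2, 6 and 8 h). The 48 libraries fall into 16 groups of 3 by maternal treatment, time and experiment. The 0 h group is the only uninfected one, so infection, handling of the larva and time of sampling change together in every comparison with 0 h. The labels do not say whether a library holds 1 larva or several. The p-values therefore measure the spread between these samples, which may be technical in part.

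The deposited values are raw read counts per gene model, one table per library, without normalization. Per the labels, libraries were made from poly-A RNA with a TruSeq v2 kit and read on an Illumina HiSeq. The authors' processing notes name FastQC, TopHat2, HTSeq and DESeq2 without versions, and the genome build is not given in the sources used here. Every table held the same 16541 gene models, of which 1137 had no count in any library.

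Totals ranged from 3.7 to 13.03 M counts per library, with a median of 6.66 M. The detection floor, taken as 3 counts per library, lay between 0.23 and 0.812 CPM (counts scaled to library size), and it covers counting error only. No 2 libraries of a group were duplicates: across 48 pairs of replicates, the chi-square per degree of freedom was 44.6 or more. Replicate numbers shared between groups were checked as possible pairs. Libraries that share a number had a mean correlation of residuals of 0.042 in experiment 1 and -0.019 in experiment 2, so the numbers were treated as not pairing the samples.

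Gene models were given names through the identifiers that the RefSeq annotation of assembly icTriCast1.1 (strain GA2) lists as synonyms. That linked 58 models, of which 52 were tested and 40 carry more than a locus number; most models have no name here, and positions are not given because the counts come from another annotation. Before the data were examined, 25 gene lists were fixed, among them antimicrobial peptides, pathogen recognition, Toll and Imd signalling, melanization and markers of fat body, muscle, gut and hemocytes. The lists were defined by words in gene names or product descriptions, and the reference gives symbols without descriptions. Matched on those words, 24 lists had no member and the heat shock list had 2, below the 5 set for a set test, so the list tests were not run. Genes known by symbol alone, such as CYP9Z4 or HEX2, were thus missed by the lists for their families, and no set test was run on the name groups below. The few named genes were grouped by name alone, before any test, into hexamerins (3), heat shock protein 68 (2), cytochrome P450 (5, of which 4 tested), mitochondrial respiration (5), stress and immune signalling (3), and neuropeptides and receptors (5).

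Counts were analysed with edgeR 4.0.16 in R 4.3.3. Models passing filterByExpr with the 16 groups were tested, 11351 in all. Libraries were scaled by TMM factors (0.741 to 1.26), and a quasi-likelihood model with 16 group means was fitted to all 48 libraries. The biological coefficient of variation was 41.8%. Each comparison was taken within experiment and averaged over the experiments that have the time. A model was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The joint test of maternal treatment by infection used 6 contrasts together. Set tests used camera, with a preset correlation of 0.01 and with an estimated one, and fry, from limma 3.58.1, on log2 CPM with a prior count of 2. Response sets are the models that rose or fell at 6 h, by at least 1 on the log2 scale, in a fit of the 24 libraries of one experiment, and were scored and tested in the other. The comparison of 6 h with 2 h, the response scores and the response sets were added after the data were seen.

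Named genes were chosen by a rule fixed before the data were examined: a name in the reference, a mean of at least 5 CPM, an adjusted p under 0.05, and for infection the same sign in every maternal treatment and experiment that has the time. Genes known by a locus number alone were counted but not described. Models without a name are given by identifier, at most 2 risen and 2 fallen per comparison, and were chosen after their values were seen.

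The model was tested on simulated data: 100 models were given a log2 change of 1 and another 100 a change of 2. Counts were drawn independently from a single mean level per model over all 48 libraries, with the fitted dispersions. Such data hold no other difference between groups or experiments and no library that stands apart, so the shares recovered need not hold in the real data. At a change of 2 it recovered 95% of them for infection at 6 h, 80% at 12 h, 76% for maternal treatment at 0 h and 73% at 12 h. At a change of 1 it recovered 67%, 46%, 53% and 24%. In the same order, 6, 3, 3 and 8 models that had been given no change were called.

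The choices above were each exchanged in turn: DESeq2 1.42.0, DESeq2 size factors, library totals without TMM, no filter beyond 1 count, a filter of 10 counts in 24 libraries, robust dispersions, an absolute log2 change of at least 1, an additive experiment term, each experiment alone, only the groups compared, the replicate number as a block, and each library left out. Leaving out the 3 libraries farthest along the second principal component was added after the data were seen. Most counts were compared with those from other splits of the same libraries into groups of the same sizes. This was not done for the values of one experiment at times or averages that both share, except maternal treatment at 0 h in experiment 1, or for the difference in response at 2, 6 and 8 h taken singly.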

Results

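Transcript levels were read in 48 libraries of beetle larvae, 3 for each of 16 combinations of maternal treatment, time after infection and experiment. Totals lay between 4.5 and 13.03 M counts in the 24 libraries of experiment 1 (median 6.42 M) and between 3.7 and 8.862 M in the 24 of experiment 2 (median 6.97 M). The medians for unprimed and primed larvae were 6.66 and 6.71 M. Each library held counts for 11879 to 13005 gene models, and its 10 most abundant models took 8.09 to 22.6% of its counts. The first 2 principal components of log2 CPM held 18.5 and 16% of the variance. Unprimed 8 h replicate 1 of experiment 2 stood apart from every other library, with a score of 146 on the second component. Next came unprimed 0 h replicate 7 and primed 6 h replicate 6 of experiment 1, with scores of 76.2 and 67.9.

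**Figure D1:**
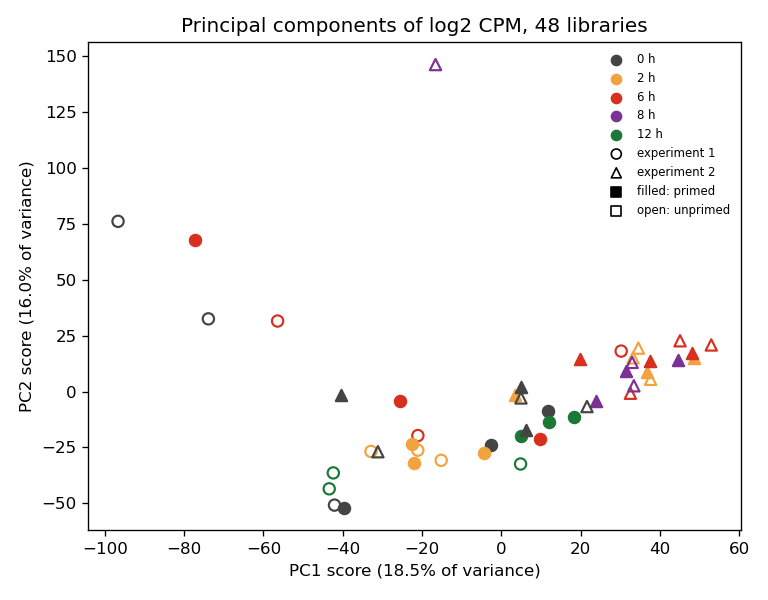
Scores of the 48 libraries on the first 2 principal components of log2 CPM, colored by hours after infection, with circles for experiment 1, triangles for experiment 2, filled symbols for primed and open ones for unprimed larvae. One unprimed 8 h library lies at 146 on the second axis, away from all others.

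The first question was how larvae respond to infection. At 2 h the neuropeptide gene RYa (LOC100750223, TC008650), which encodes RYamide peptides, rose by 1.32 on the log2 scale (SE 0.36, adjusted p = 0.00847). Its mean went from 9.34 ± 6.34 to 16.5 ± 5.78 CPM in experiment 1 and from 5.50 ± 3.21 to 21.3 ± 11.2 CPM in experiment 2 (SD, n = 6 at each time). The AP-1 subunit gene kay (TC011870), the beetle homolog of Fos, rose by 0.47 (SE 0.13, adjusted p = 0.00872), from 158 ± 23.5 to 270 ± 38.3 CPM in experiment 1 and from 227 ± 32.1 to 256 ± 75.8 CPM in experiment 2. The acyl-CoA desaturase gene Z9desB (TC016415) fell by 2.29 (SE 0.77, adjusted p = 0.0335), from 826 ± 1312 to 335 ± 219 CPM and from 251 ± 297 to 32.9 ± 52.8 CPM. None of the 3 hexamerins, the 2 heat shock protein 68 genes, the 4 tested cytochrome P450 genes or the 5 mitochondrial respiration genes passed the test at 2 h. Among models without a name, chosen after their values were seen, TC002832 went from 1.79 ± 1.46 to 355 ± 108 CPM in experiment 1 and from 2.62 ± 3.14 to 294 ± 149 CPM in experiment 2. TC013480 went from 75.4 ± 132 to 3755 ± 936 CPM and from 30.4 ± 12.2 to 3867 ± 858 CPM. TC001161 dropped in both experiments, from 109 ± 109 to 11.3 ± 6.09 CPM and from 81.4 ± 75 to 7.07 ± 4.37 CPM. In all, 2145 of 11351 tested models changed, 1084 up and 1061 down, of which 504 rose and 174 fell by at least 2-fold.

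The balance of rises and falls at 2 h depended on scaling, since library totals without TMM gave 862 up and 1325 down. kay was called in experiment 1 but not in experiment 2 alone (0.17, adjusted p = 0.669), and RYa was not called in experiment 1 alone (0.79, adjusted p = 0.316). The call on Z9desB held in 22 of 36 alternatives and in neither experiment alone (-1.29, adjusted p = 0.451, and -3.29, adjusted p = 0.0699). It ended with the replicate number as a block (0.157), with only the groups compared (0.0839) and without any 1 of 10 libraries, with adjusted p from 0.0526 to 0.261. They were, in experiment 1, unprimed 0 h replicate 6, unprimed 2 h replicates 4 and 5, primed 0 h replicate 3 and primed 2 h replicate 5. In experiment 2 they were unprimed 0 h replicate 3, unprimed 2 h replicate 1, primed 0 h replicate 3 and primed 2 h replicates 1 and 2.

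**Figure D2:**
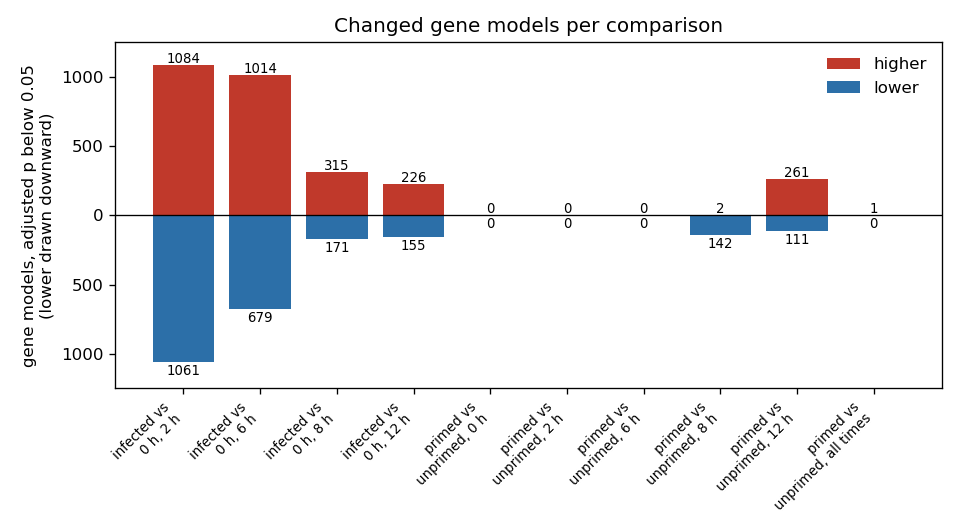
Number of gene models called changed at an adjusted p under 0.05 in each comparison with 0 h and in each comparison of primed with unprimed larvae, with rises drawn upward and falls downward. Against 0 h, 2145 models differed at 2 h and 1693 at 6 h; between primed and unprimed larvae edgeR called 0 at 0, 2 and 6 h, 144 at 8 h, where most of the falls lay in 1 library, and 372 at 12 h.

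At 6 h the storage protein genes HEX2 (TC006769) and HEX1B (TC005377) fell, by 2.56 (SE 0.72, adjusted p = 0.0136) and by 2.91 (SE 0.88, adjusted p = 0.0224). HEX2 went from 22375 ± 19480 to 6014 ± 6390 CPM in experiment 1 and from 24101 ± 11006 to 2894 ± 3663 CPM in experiment 2. HEX4 (TC005375), the third hexamerin, was at -1.49 with an adjusted p of 0.234. The inducible chaperone gene hsp68b (TC009126) rose by 1.71 (SE 0.48, adjusted p = 0.0136), from 5.29 ± 7.42 to 12.3 ± 16.1 CPM and from 1.48 ± 0.672 to 5.51 ± 3.35 CPM. The related gene hsp68a (TC009706) was at 1.00 with an adjusted p of 0.0614. RYa rose by 1.60 (SE 0.36, adjusted p = 0.00272), Z9desB fell by 3.58 (SE 0.82, adjusted p = 0.00285), and kay did not pass (0.23, adjusted p = 0.233). CYP9Z4 (TC006444) rose by 0.90 (SE 0.27, adjusted p = 0.0209), from 98.7 ± 55.0 to 206 ± 100 CPM and from 187 ± 66.0 to 291 ± 61.9 CPM, while the 3 other tested cytochrome P450 genes did not pass. SdhB (TC011988), the iron-sulfur subunit of succinate dehydrogenase, fell by 0.38 (SE 0.12, adjusted p = 0.025), and the other 4 mitochondrial respiration genes did not pass. The epsin-related gene lqfR (TC012168) rose by 0.29 (SE 0.09, adjusted p = 0.0212). Among unnamed models, TC002832 rose by 6.78 (SE 0.56) and TC010350 by 6.60 (SE 0.66, 3.83 ± 3.25 to 212 ± 223 CPM in experiment 1 and 3.20 ± 1.90 to 585 ± 402 CPM in experiment 2). In all, 1693 models changed, 1014 up and 679 down, with 320 rises and 227 falls of at least 2-fold.

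Library totals without TMM gave 1164 up and 390 down at 6 h, and the contrast gave 554 models in experiment 1 and 1023 in experiment 2. Taken 1 experiment at a time, the calls on HEX1B, hsp68b and lqfR held in neither; that on HEX2 was at adjusted p = 0.232 and 0.0504, that on SdhB at 0.282 and 0.0732. RYa (0.171), Z9desB (0.107) and CYP9Z4 (0.0656) were not called in experiment 1 alone, and CYP9Z4 not in experiment 2 alone either (0.314). Another cytochrome P450 gene, CYP346B2 (TC014360), was called lower in experiment 2 alone, at -2.35 (SE 0.72, adjusted p = 0.0357), and not in experiment 1 alone. Without unprimed 0 h replicate 6 of experiment 1 the calls on HEX2 (adjusted p = 0.0518), HEX1B (0.162) and SdhB (0.0563) ended. hsp68b was not called without unprimed 6 h replicate 6 (0.0686) or primed 6 h replicate 6 (0.109) of experiment 1. SdhB was also lost without unprimed 6 h replicate 6 (0.0612) or primed 0 h replicate 3 (0.0692) of experiment 1, or unprimed 0 h replicate 3 of experiment 2 (0.0588), and with library totals (0.0601). With the replicate number as a block the calls on hsp68b (0.074), HEX1B (0.0831), CYP9Z4 (0.0724) and SdhB (0.0745) ended, and with only the groups compared those on hsp68b (0.0565), lqfR (0.0567) and SdhB (0.0613).

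**Figure D3:**
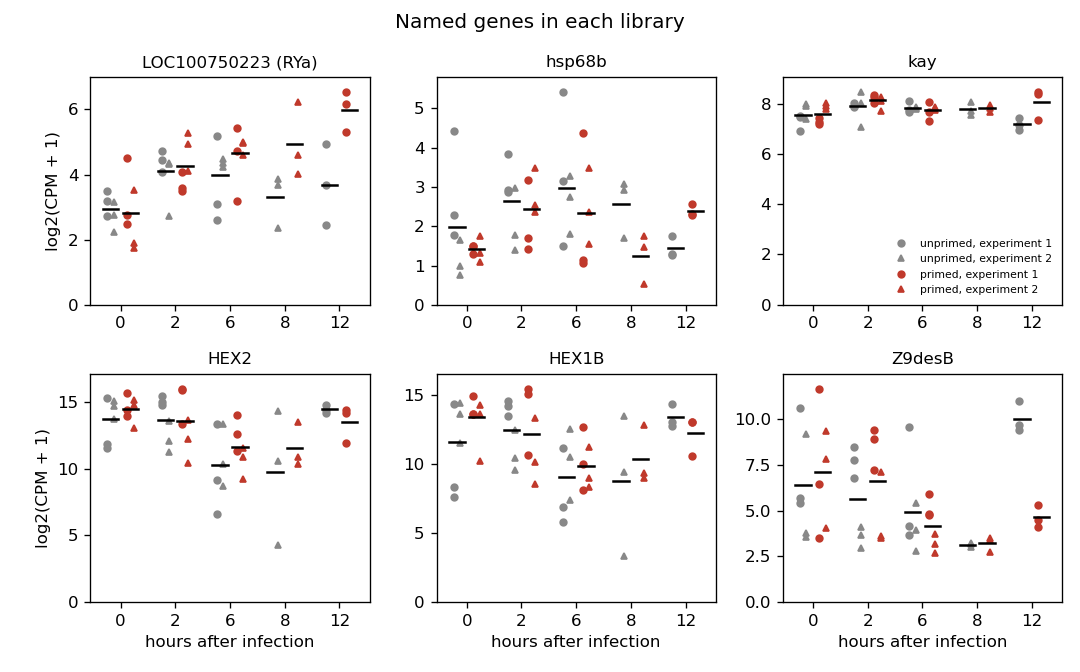
Levels of 6 named genes as log2(CPM + 1) against hours after infection, one symbol per library, gray for unprimed, red for primed, circles for experiment 1 and triangles for experiment 2; black bars are means of 3 or 6 libraries. RYa is higher at every time after infection, HEX2, HEX1B and Z9desB are lower at 6 h, and Z9desB at 12 h averages 1188 CPM in unprimed and 25.4 CPM in primed larvae.

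At 8 h, in experiment 2 alone, Z9desB fell by 4.91 (SE 1.23, adjusted p = 0.0167), from 251 ± 297 to 8.18 ± 1.69 CPM (SD, n = 6). SdhB fell by 0.60 (SE 0.16, adjusted p = 0.0315), from 290 ± 65.1 to 193 ± 40 CPM, and RYa rose by 1.77 (SE 0.52, adjusted p = 0.043), from 5.50 ± 3.21 to 23.6 ± 25.4 CPM. None of the hexamerin, heat shock protein 68 or cytochrome P450 genes passed; HEX2 was at -2.04 (adjusted p = 0.264). TC010350 rose by 7.35 (SE 0.96), from 3.20 ± 1.90 to 536 ± 322 CPM. The count was 486, with 315 up and 171 down; it was 250 without unprimed 0 h replicate 3 and 236 without primed 8 h replicate 3, and library totals gave 483 up and 118 down with the median of all models 0.138 higher. Z9desB lost its call without primed 8 h replicate 2 or 3 or unprimed 0 h replicate 3 (adjusted p from 0.0542 to 0.174), with the replicate block (0.0872) or with only the groups compared (0.058). SdhB lost it without unprimed 8 h replicate 1 or 2, primed 8 h replicate 1 or 2, unprimed 0 h replicate 3 or primed 0 h replicate 2 or 3 (0.0589 to 0.133). It was also lost with library totals (0.0603), no filter (0.0507), only the groups compared (0.076), the additive experiment term (0.0516) and the 3 libraries farthest along the second component left out (0.0705), so it held in 10 of 22 alternatives. RYa lost it without unprimed 8 h replicate 2 or 3, primed 8 h replicate 3, any unprimed 0 h library or primed 0 h replicate 1 or 2 (0.0712 to 0.208), and with no filter (0.0533), only the groups compared (0.107) or the additive term (0.0701), and held in 11 of 22. The 8 h calls on SdhB and RYa are therefore not secure.

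At 12 h, in experiment 1 alone, RYa rose by 1.79 (SE 0.51, adjusted p = 0.0433), from 9.34 ± 6.34 to 41.0 ± 33.9 CPM. It was the only one of the 52 named models tested to pass at this time. Z9desB was at -2.17 (adjusted p = 0.292) and HEX2 at -0.26 (adjusted p = 0.932). TC000517 rose by 7.87 (SE 0.90), from 11.9 ± 7.15 to 3013 ± 2389 CPM, and TC010350 by 7.79 (SE 0.98), from 3.83 ± 3.25 to 1147 ± 1008 CPM. The count was 381, with 226 up and 155 down, and library totals turned this balance to 168 up and 207 down. It was 222 without primed 0 h replicate 6, 165 with the replicate block and 645 by DESeq2. With only the groups compared it was 97, of which 88 were up and 9 down. Against their own 0 h groups, 662 models changed in primed larvae (328 with the replicate block) and 52 in unprimed larvae (3 with the block, 228 by DESeq2, 2 without the 3 libraries farthest along the second component). The first count fell to 315 and 247 without primed 0 h replicates 4 and 6 and to 385 and 440 without primed 12 h replicates 3 and 7. The second ranged from 2 without unprimed 0 h replicate 7 to 575 without unprimed 0 h replicate 6, and moved by more than 1.5 times without any 1 of its 6 libraries (98 without unprimed 0 h replicate 1, and 21, 17 and 5 without unprimed 12 h replicates 1, 2 and 7). Across models the 12 h changes of unprimed and primed larvae correlated at r = 0.0602 (rho 0.0270). The same r was 0.563 at 2 h, 0.429 at 6 h and 0.191 at 8 h. At 12 h 11 models were among both the 16 and the 424 that rose, where independent lists would share 0.598. Of the 36 and 238 that fell 0 were shared, and 4 models went opposite ways. RYa was not called without unprimed 0 h replicates 1, 6 or 7, primed 0 h replicates 4 or 6, unprimed 12 h replicates 2 or 7, or primed 12 h replicates 3 or 7 (adjusted p from 0.0511 to 0.199). It was not called either with no filter (0.0549), the replicate block (0.121), only the groups compared (0.157) or the 3 libraries farthest along the second component left out (0.0802), so the call held in 9 of 22 alternatives and is not secure.

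The next question was whether the response recurred when the experiment was repeated. Of 731 models that rose at 2 h in experiment 1 and 663 in experiment 2, 401 were shared, where independent lists would share 42.7. Of 1029 that fell in experiment 1 and 258 in experiment 2, 66 were shared, against 23.4, and 1 model went opposite ways. Across models, which are not independent replicates, the log2 changes correlated at r = 0.437 (rho 0.307) at 2 h and r = 0.376 (rho 0.280) at 6 h. At 6 h 167 models were among both the 346 and the 659 that rose, against 20.1, and 25 among both the 208 and the 364 that fell, against 6.67. A test of the difference between experiments found 23 models at 2 h, none of them named, and 0 at 6 h by edgeR, where 1740 had an unadjusted p under 0.05 and DESeq2 called 38. The largest rise in excess in experiment 2 was TC014951, by 4.42 (SE 0.72, adjusted p = 0.00573). Library totals raised the count at 2 h to 1430, with the median of all models 0.338 higher. It was 345, 6 and 9 without primed 0 h replicates 3, 4 and 6 of experiment 1, 118 and 11 without unprimed 0 h replicates 6 and 7, 13, 14 and 11 without unprimed 2 h replicates 4, 5 and 6, and 7 and 38 without primed 2 h replicates 3 and 5. In experiment 2 it was 39 and 8 without unprimed 2 h replicates 1 and 2, and 13 and 11 without unprimed 0 h replicates 2 and 3.

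The third question was whether larvae of primed mothers differ from larvae of unprimed mothers. Among the named genes, no hexamerin, heat shock, cytochrome P450, respiration, signalling or neuropeptide gene passed at 0, 2 or 6 h, in uninfected or infected larvae. At 0 h HEX2 was at 0.40 (SE 0.96), RYa at 0.14 (SE 0.52) and kay at 0.05 (SE 0.18), primed over unprimed. edgeR called 0 models at 0 h (1297 with an unadjusted p under 0.05, DESeq2 66), 0 at 2 h (315, DESeq2 9) and 0 at 6 h (330, DESeq2 7). Within experiment 1 at 0 h it called 118, 30 higher and 88 lower in primed larvae, where DESeq2 called 508 and the replicate block left 0, and within experiment 2 it called 0 (551 with an unadjusted p under 0.05, DESeq2 7). Across models the 0 h differences of the 2 experiments had r = -0.209. At 2 h the experiments gave 0 and 1 model, and at 6 h they gave 0 and 0. The count at 0 h became 266 without unprimed 0 h replicate 6 and 1 without replicate 1 of experiment 1, and 2 and 4 without unprimed and primed 0 h replicate 3 of experiment 2. The count of 118 became 0 without unprimed replicate 7 or primed replicates 4 or 6, 485 without primed replicate 3 and 1023 without unprimed replicate 6.

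Averaged over all times, 1 model differed between primed and unprimed larvae (888 with an unadjusted p under 0.05, DESeq2 17). This was TC009881, named after its value was seen, which was higher in primed larvae by 3.36 (SE 0.48, adjusted p = 0.000373). Its mean over the 48 libraries was below 5 CPM, so the size of this difference rests on low counts. By time it was 4.51, 3.38, 3.33 and 3.59 at 0, 2, 6 and 8 h but 0.81 (SE 1.05, adjusted p = 0.792) at 12 h, with no call at any single time. Its difference was 2.20 (SE 0.61, adjusted p = 0.136) in experiment 1 and 4.52 (SE 0.72, adjusted p = 0.00442) in experiment 2. The count was 0 without primed 6 h replicate 1 of experiment 1 and 6 without unprimed 8 h replicate 2. It was 2 or 3 without unprimed 0 h replicate 1, unprimed 2 h replicate 5, unprimed 12 h replicate 2, primed 0 h replicate 3, primed 2 h replicate 5 or primed 6 h replicate 6 of experiment 1, and without unprimed 8 h replicate 3, primed 2 h replicate 3 or primed 6 h replicate 1 of experiment 2. Within experiment 1 the count was 17 and within experiment 2 it was 1.

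At 8 h 144 models differed, 2 higher and 142 lower in primed larvae, and most of these falls lay in 1 library. Over the 142 models, unprimed 8 h replicate 1 stood 6.48 (log2, median) above the mean of the other 5 libraries, whereas unprimed replicates 2 and 3 were at -1.25 and -1.33. In that library TC008208 had 5212 CPM and TC013817 had 1601 CPM, against at most 0.739 and 0.106 CPM in the other 5. The hexamerins differed there too, with HEX4 at 1398 CPM against 2.11 to 27.9 CPM elsewhere at 8 h, HEX2 at 18.7 CPM against 1323 to 19797 CPM, and HEX1B at 9.13 CPM against 507 to 11182 CPM. None of the 52 named models passed at 8 h. Without unprimed replicate 1 the count was 0, and the fitted differences in TC008208 and TC013817 changed sign, between libraries with at most 7 and 1 counts of them, where a size has no meaning. The count was also 0 without primed replicates 1 or 3, 1 without primed replicate 2, and 290 and 282 without unprimed replicates 2 and 3.

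At 12 h primed larvae had more kay (282 ± 105 against 145 ± 24.5 CPM; SD, n = 3 each), a difference of 0.96 (SE 0.26, adjusted p = 0.03). They had less SdhB (264 ± 13.9 against 467 ± 137 CPM), by -0.82 (SE 0.23, adjusted p = 0.0419). Z9desB stood at 25.4 ± 11.5 CPM in primed and 1188 ± 747 CPM in unprimed larvae (-5.55, SE 1.79, adjusted p = 0.0812). RYa stood at 66.7 ± 26.8 and 15.3 ± 12.9 CPM (2.13, SE 0.72, adjusted p = 0.1); neither passed. Of the name groups, 1 of 3 signalling genes was higher, 1 of 5 respiration genes was lower, and no hexamerin, heat shock, cytochrome P450 or neuropeptide gene passed. The models TC005093 and TC005096, chosen after their values were seen, had 936 ± 450 and 844 ± 174 CPM in primed larvae against 2.34 ± 0.699 and 3.10 ± 1.51 CPM in unprimed larvae. In all, 372 models differed, 261 higher and 111 lower, with 223 and 82 by at least 2-fold. Of the 261, 127 had risen at 6 h after infection in experiment 2, whose libraries are separate, where 15.2 are expected of independent lists; of the 111, 26 had fallen there, against 3.56. The count was 122 and 158 without unprimed replicates 1 and 7 and 166 without primed replicate 7. It was 84 with only the groups compared, 209 with the replicate block and 584 by DESeq2. kay was not called without unprimed replicates 1 or 7 or primed replicates 3 or 7 (adjusted p from 0.0985 to 0.2), with the replicate block (0.146) or with only the groups compared (0.295), and held in 10 of 16 alternatives. SdhB was not called without unprimed replicates 1 or 7 or any primed library (0.0715 to 0.318), with no filter (0.0647) or with only the groups compared (0.35), and held in 9 of 16.

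Whether infection acts differently in primed larvae was tested directly. The joint test over all times found 46 models (1225 with an unadjusted p under 0.05), none of them among the 52 named. DESeq2 gave 295, the additive experiment term 160 and the replicate block 11. At 12 h the difference in response was 0.99 for kay (SE 0.37, adjusted p = 0.175) and -0.56 for SdhB (SE 0.33, adjusted p = 0.42). The lowest p in the joint test belonged to TC001231 and TC000822, named after their values were seen (adjusted p = 2.57e-05 and 0.000117). At 12 h TC000822 had 172 ± 93.6 CPM in primed and 0.718 ± 0.392 CPM in unprimed larvae, and TC001231 had 138 ± 49.8 and 27.7 ± 3.21 CPM (SD, n = 3). By time, edgeR called 146 at 12 h (121 higher and 25 lower; DESeq2 380, replicate block 38), 0 at 2 h (768 with an unadjusted p under 0.05, DESeq2 3), 0 at 6 h (883, DESeq2 26) and 0 at 8 h (1009, DESeq2 127). The joint count was 186 without unprimed 0 h replicate 6, 24 without unprimed 12 h replicate 1 and 71 without primed 6 h replicate 3 of experiment 1, and 162 and 134 without unprimed 8 h replicates 2 and 3. The count at 12 h was 654 and 58 without unprimed 0 h replicates 6 and 7, 97 and 81 without primed 0 h replicates 4 and 6, 97 without unprimed 12 h replicate 7, and 324 and 89 without primed 12 h replicates 6 and 7. At 2 h it was 5 without unprimed 0 h replicate 6 of experiment 1, at 8 h it was 152 and 154 without unprimed 8 h replicates 2 and 3, and at 6 h it was 29 and 1 without unprimed 0 h replicate 6 and primed 0 h replicate 3 of experiment 1 and 2 without unprimed 6 h replicate 2 of experiment 2.

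A response score, chosen after the counts were seen, gave each library its mean log2 level over the models that had risen by at least 2-fold at 6 h in the other experiment, set to 0 in the uninfected libraries. In experiment 1 (328 models) it reached 1.74 ± 0.18 in unprimed and 1.53 ± 0.06 in primed larvae at 2 h, and 1.41 ± 0.59 and 1.20 ± 0.42 at 6 h (SD, n = 3). At 12 h it was 0.42 ± 0.55 in unprimed and 2.13 ± 0.21 in primed larvae. All 3 primed libraries lay above all 3 unprimed ones, a difference of 1.71 with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 can give (0.5 adjusted over 10 tests). In experiment 2 (121 models) the scores at 8 h were 2.33 ± 0.64 and 2.53 ± 0.47 (difference 0.21, exact p = 0.8). Unprimed 8 h replicate 1, the library that stood apart, was at 1.64, and unprimed replicates 2 and 3 were at 2.44 and 2.90. Over both experiments, primed minus unprimed had an exact p of 0.985 at 0 h, and was -0.21 at 2 h (exact p = 0.225) and -0.26 at 6 h (exact p = 0.32). The 0 h value averages opposite differences. In experiment 1 all 3 primed libraries lay above all 3 unprimed ones before infection too, with means of 0.12 and -0.12. In experiment 2 the means were -0.12 and 0.12. As a set, the 325 of these models tested in a fit of experiment 1 alone were higher in primed larvae at 12 h (camera, adjusted p = 3.49e-57 with the preset correlation; adjusted p = 0.0078 with an estimated correlation; fry adjusted p = 0.000244; 16 set tests). The 272 models that had fallen were lower with the preset correlation (adjusted p = 2.56e-16) but not with an estimated correlation (adjusted p = 0.55; fry adjusted p = 0.188). The call at 12 h for the risen set was the only one of the 16 to hold with an estimated correlation. With the preset correlation camera also called the risen set in uninfected larvae, higher in primed larvae of experiment 1 (adjusted p = 0.037) and lower in those of experiment 2 (adjusted p = 0.0119). The estimated correlations were 0.0707 to 0.305, above the preset 0.01, so the p-values with the preset one are too small.

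**Figure D4:**
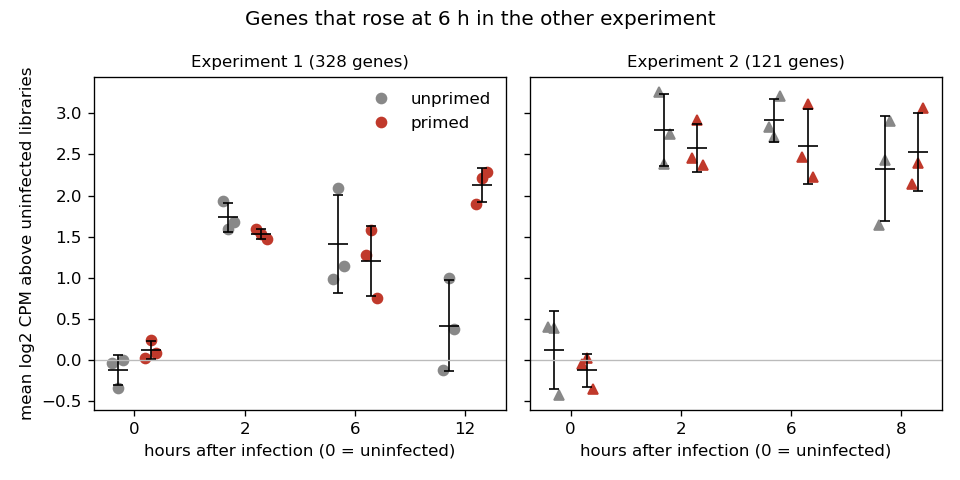
Response score of each library against hours after infection, gray for unprimed and red for primed larvae, with bars for the mean and SD of 3 libraries; the score is the mean log2 CPM above the uninfected libraries over models that rose at 6 h in the other experiment. At 12 h in experiment 1 the primed larvae average 2.13 and the unprimed 0.42.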

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

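The comparison of 6 h with 2 h, the counts over other splits of the libraries and the tests of a single library, of library totals and of the response score were chosen after the results were seen; the tests of differences between maternal treatments and between experiments were planned.

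Levels in infected larvae differed between 6 and 2 h, in a test of the difference between those time points. There were no uninfected larvae at either time, so a change in the response cannot be told apart from one with age or time since handling. SdhB was lower at 6 h, by -0.39 (SE 0.12, adjusted p = 0.0282), and the call held in 25 of 32 alternatives. It ended with library totals (-0.25, adjusted p = 0.0896), with the replicate block (0.0611), without unprimed 6 h replicate 6 (0.055) or primed 2 h replicate 5 (0.051) of experiment 1, and without unprimed 6 h replicate 1 (0.0546), primed 2 h replicate 3 (0.0574) or primed 6 h replicate 4 (0.0534) of experiment 2. ND-23 (TC015022), a complex I subunit at -0.53 (SE 0.18, adjusted p = 0.0482), lost its call in 23 of 32 alternatives, so that call is not secure. In all 1168 models differed, 682 higher and 486 lower at 6 h. Library totals without TMM gave 1595 higher and 328 lower, with the median of all models at 0.161 in place of 0.0211, so the balance depends on scaling. None of the 24 other splits gave any model, which argues against chance, though so few splits allow a share only just under 0.05.

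The response at 2 h differed between experiments, in a test of that difference, in 23 models, and experiment is also a batch. The most in any of the other 40 splits was 20. Those splits exchanged libraries between the experiments, which differed in 1844 of 11351 models at 0 h, so their mixed groups take in that difference. They therefore cannot exclude chance for the 23 models. The count was 13 without a filter and 2 with the replicate block. It was 6, 9 and 345 without primed 0 h replicates 4, 6 and 3 of experiment 1, 11 and 118 without unprimed 0 h replicates 7 and 6, 13, 14 and 11 without unprimed 2 h replicates 4, 5 and 6, and 7 and 38 without primed 2 h replicates 3 and 5. In experiment 2 it was 39 and 8 without unprimed 2 h replicates 1 and 2, and 13 and 11 without unprimed 0 h replicates 2 and 3. In 10 of these 14 cases it lay below the 20 of another split. That split kept every library and mixed the experiments, so 20 is no measure of chance for these counts.

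The response differed between primed and unprimed larvae in 46 models by the joint test over times and in 146 models at 12 h, again by tests of the difference. Chance cannot be excluded for either: 6 of 61 splits within time and experiment gave at least 46 (highest other 206), and 7 of 61 gave at least 146 (highest other 606). Splits that call several times the real count point to a structure of the samples, which single libraries would also give; which of these it is was not tested. The joint count ranged from 24 without unprimed 12 h replicate 1 to 186 without unprimed 0 h replicate 6, and the 12 h count from 58 to 654 without unprimed 0 h replicates 7 and 6.

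A pattern weighed further is the difference at 12 h, where primed larvae had 261 models higher and 111 lower, kay among the first and SdhB among the second. A single library does not account for the higher response: over models that rose in experiment 2 the score of primed larvae was higher by 1.71 (SE 0.34), and by 1.44 (SE 0.28) without unprimed replicate 1, the lowest with any 1 of the 6 left out, though the count of 372 was 122 and 158 without unprimed replicates 1 and 7 and 166 without primed replicate 7. Sequencing depth does not either, with a ratio of mean totals, primed over unprimed, of 0.985. Whether infection took hold in the unprimed larvae cannot be told apart from an effect of the mothers' treatment: 2 of the 3 unprimed libraries at 12 h scored above 0.247, the highest score of an uninfected library of experiment 1, and the third lay below. Both stay open, the effect of the mothers' treatment as untested. Only 1 experiment has this time, and its 10 splits (real count 372, highest other 214) are too few for a share under 0.05.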

How the results depend on the processing

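The alternative that left out the 3 libraries farthest along the second principal component, those of the response score, the comparison of 6 h with 2 h and the models without a name were chosen after the data were seen; the other settings were planned. Of the named and listed models' alternatives, 4 reversed: without unprimed 8 h replicate 1 the 8 h differences between primed and unprimed larvae were 1.78 for TC008208 and 1.62 for TC013817, and without the 3 libraries 1.78 and 1.62, because the library that held the high values was gone; the others held at most 7 counts of either model, so these sizes have no meaning. Without primed 8 h replicate 2 the fit gave -16.53 and -14.83 (adjusted p = 0.0564 and 0.0912), set by libraries near 0 and no bound. The camera test with an estimated correlation on the fixed gene lists was not run, since by the match of words in names no list had 5 members. Depth limits models near the floor of 0.23 to 0.812 CPM, and at a log2 change of 1 the simulated data recovered 24% to 67% of models.

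Where a count moved by more than 1.5 times the cause was not tested. DESeq2 gave 807 and 645 models for infection at 8 and 12 h, 66, 9, 7 and 584 for maternal treatment at 0, 2, 6 and 12 h, 17 over all times, 295 for the joint difference in response, and 201 and 38 for the difference between experiments at 2 and 6 h. Library totals without TMM gave 1430 for the latter at 2 h and 2 over all times. Requiring a log2 change of at least 1 left 678, 547 and 224 for infection at 2, 6 and 12 h and 15 for the difference between experiments at 2 h. No filter gave 13 for that difference, and the stricter filter left 33 for maternal treatment at 8 h. An additive experiment term gave 1 at 0 h, 11 over all times and 160 for the joint test. Only the groups compared gave 268 and 97 for infection at 8 and 12 h, and 1, 1, 0 and 84 for maternal treatment at 0, 2, 8 and 12 h. Experiment 1 alone gave 554 for infection at 6 h, 118 for maternal treatment at 0 h and 17 over all times; experiment 2 alone gave 921 and 1023 for infection at 2 and 6 h and 1 for maternal treatment at 2 h. Without the 3 libraries maternal treatment at 8 h gave 0.

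Fitted as a block, the replicate number gave 1699, 1202, 344 and 165 for infection at 2, 6, 8 and 12 h, 0 and 209 for maternal treatment at 8 and 12 h, 2 over all times, 11 for the joint test and 2 for the difference between experiments at 2 h. The numbers showed no sign of pairing the samples, and 7 of 48 libraries correlated best with one of the same number. Within unprimed and primed larvae the block gave 726 and 561 for infection at 2 h and 354 and 248 at 6 h, and 63 in unprimed larvae at 8 h, where the stricter filter gave 159 and leaving out the 3 libraries 74. DESeq2 gave 850 in primed larvae at 6 h, and 446 and 297 in unprimed and primed larvae at 8 h, where leaving out the 3 libraries gave 210 in primed larvae.

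Leaving out 1 library at a time gave 1791 to 2463, 1193 to 1882, 236 to 540 and 222 to 509 models for infection at 2, 6, 8 and 12 h. For maternal treatment it gave 0 to 266 at 0 h, 0 at 2 and 6 h, 0 to 290 at 8 h, 122 to 501 at 12 h, 0 to 6 over all times and 24 to 186 for the joint test. For the difference between experiments it gave 6 to 345 at 2 h and 0 at 6 h, and the 12 h difference in response score stayed between 1.44 and 2.00. Over all alternatives to the leading counts and the score difference, 335 stayed within 1.5 times or 1 SD and 86 did not. For single models and secondary counts, 1391 stayed within 1.5 times or kept their call, 275 kept their direction and lost the call, and 103 counts moved further. A count of 0 that stayed 0, as for maternal treatment at 2 and 6 h, was taken as unchanged in both tallies. The shares that stayed therefore overstate how stable the counts above 0 were.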

Other observations

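The tests of the hexamerins, of the spread of scores, of the standout library at 8 h and of a single library at 0 h, the score at 12 h against 0 h and the counts over other splits were chosen after the results were seen; the tests of consecutive model numbers and of the overlap between the 0 h and 8 h lists were set before theirs.

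The storage protein transcripts HEX2 and HEX1B varied together between libraries of the same group. Deviations from the group means of log2 CPM correlated at r = 0.926 in experiment 1 and r = 0.955 in experiment 2 (24 libraries each; rho 0.947 and 0.941; permutation p = 1.0e-05 and 2.0e-05, adjusted p = 6.0e-05 for both over 6 relations). Without the 2 libraries farthest from the median, r was 0.971 and 0.921. For HEX4 the test shows neither joint variation nor its absence: its r with HEX2 was -0.233 and -0.493 (rho -0.310 and -0.352; permutation p = 0.48 and 0.159, adjusted p = 0.48 and 0.196). Its r with HEX1B was -0.491 and -0.576 (rho -0.396 and -0.457; permutation p = 0.163 and 0.0591, adjusted p = 0.196 and 0.118), and without the 2 farthest libraries these 4 values were 0.0348, -0.189, -0.228 and -0.317. Libraries of 1 group may thus differ in a shared state of the larvae such as developmental stage, and reads shared between similar hexamerin genes stay open as another source of the high r; neither was tested.

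Models with consecutive numbers rose together at 6 h. Of 8847 pairs of tested models whose numbers follow each other, 128 had both members among the 1014 that rose, against a mean of 70.6 and a highest value of 102 in 10000 random relabellings (permutation p = 1e-04, the smallest they can give). If numbers follow position, as in many gene sets, this is consistent with groups of neighboring genes responding alike; paralogs that share reads stay open as a source.

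Infected libraries deviated from their group's mean response score by 0.279 on average and uninfected ones by 0.184, a ratio of 1.51 (permutation p = 0.135; 2.19 in experiment 1 and 1.22 in experiment 2). The test does not show that infected groups vary more, and does not exclude it.

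The falls in primed against unprimed larvae at 8 h lay mostly in unprimed replicate 1 of experiment 2. Without that library the median difference over the 144 models, in the called direction, went from 2.28 to 0.0396 (log2). Shallow sequencing is argued against, since its total was 0.709 of the median of the other 5. A response to infection in this sample may be the source, but an uninfected library of experiment 1, unprimed 0 h replicate 7, stood 1.56 above its peers over the 142 lower models, against 6.48 for the 8 h library, which leaves this open along with a mixed or contaminated sample and a developmental difference. The response score of the 8 h library, over models that rose at 6 h in experiment 1, was 1.64. The other 5 libraries at 8 h lay between 2.15 and 3.06. HEX4, TC008208 and TC013817 were high in the 8 h library and HEX2 and HEX1B low. The 2 models higher in primed larvae, TC009162 and TC014539, kept their direction in all 16 alternatives, with log2 differences of at least 1.72 and 0.706. Their calls ended in 6 and 8 of these.

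Among uninfected larvae of experiment 1, 118 models differed between maternal treatments and none in experiment 2. Whether unprimed replicate 7 alone gave this stays open. Without it the median difference over the 118 models was 1.11 of an original 1.90 (log2), but these models were chosen with it included, and the count was 0 without it and also without primed replicates 4 or 6. It was 485 without primed replicate 3 and 1023 without unprimed replicate 6. The 88 lower models and the 142 lower at 8 h shared 2, where independent lists share 1.10 (Fisher's exact p = 0.302). The bound set before this test would argue against a shared program, but it rests on thresholded lists. Over the same 142 models unprimed 0 h replicate 7 stood 1.56 above its peers, and the next highest uninfected library of experiment 1 stood at 0.266. Primed 6 h replicate 6 of experiment 1, also far along the second principal component, stood 0.914 above its own peers, and unprimed 6 h replicate 7 stood 0.617 above them. A program shared with the 8 h library thus stays open, as do an effect of the mothers' treatment and a difference in stage.

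Other splits of the libraries were counted for further results. For infection averaged over maternal treatments, the real split gave more models than each of the 24 others at 2 h (2145, highest other 590), 6 h (1693, 36) and 8 h (486, 43). This argues against chance there, though 25 splits allow a share only just under 0.05. At 12 h 2 of 25 splits gave as many (381, highest other 396), so the count alone does not exclude chance. Other values argue against chance for the rises at 12 h averaged over maternal treatments. The score over models that rose at 6 h in experiment 2, whose libraries are separate, was higher at 12 h than at 0 h in experiment 1. The difference was 1.28 on average over maternal treatments (exact permutation p = 0.015), with 0.54 in unprimed and 2.01 in primed larvae. At 12 h 5 of 6 libraries lay above the highest uninfected one, and unprimed replicate 1 lay below, at -0.114. The average rests mostly on primed larvae and does not show a rise in unprimed larvae taken alone. Of the 226 models that rose at 12 h, 122 had risen at 6 h in experiment 2 (13.1 expected of independent lists, 1 opposite). Of the 155 that fell, 6 had fallen there at 6 h (4.97 expected) and 12 at 8 h (2.34 expected, 0 opposite), so the falls stay open. Within one maternal treatment the real count was also the highest at 2 and 6 h. At 2 h it was 1264 in unprimed larvae (24 splits) and 869 in primed larvae (22 splits), with a highest other of 0 for both. At 6 h it was 695 in unprimed larvae (24 splits, highest other 341) and 546 in primed larvae (23 splits, highest other 1). This argues against chance, least so in unprimed larvae at 6 h. The splits were too few for a share under 0.05 at 8 h (unprimed 283, highest other 151; primed 111, 1) and 12 h (unprimed 52, 90; primed 662, 61).

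Leaving out single libraries moved most of these counts within one treatment by more than 1.5 times. The 2 h count in primed larvae was 568 without primed 0 h replicate 2 of experiment 2. The 6 h count in unprimed larvae was 390 and 229 without unprimed 0 h replicate 7 and 6 h replicate 6 of experiment 1. For experiment 2 it was 322, 395 and 313 without unprimed 0 h replicate 3 and 6 h replicates 1 and 4. In 3 of these 5 cases it lay below the 341 of another split, though that split kept every library. In primed larvae at 6 h it was 302 and 350 without primed 0 h replicate 6 and 6 h replicate 1 of experiment 1, and 323, 363 and 251 without primed 0 h replicate 2 and 6 h replicates 1 and 3 of experiment 2. At 8 h the unprimed count was 106, 95 and 59 without 0 h replicates 1, 2 and 3, and 60 and 445 without 8 h replicates 1 and 2, and the primed count was 56 and 67 without 0 h replicates 1 and 3 and 50 without 8 h replicate 3. At 12 h the unprimed count was 98, 575 and 2 without 0 h replicates 1, 6 and 7, and 21, 17 and 5 without 12 h replicates 1, 2 and 7. The primed count at 12 h was 315 and 247 without 0 h replicates 4 and 6, and 385 and 440 without 12 h replicates 3 and 7.

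For maternal treatment the real counts at 0, 2 and 6 h were 0 (61 splits, highest other 151, 1 and 7), as was that of the difference between experiments at 6 h (37 splits, highest other 29). Any split matches a count of 0, so these splits say nothing for or against a difference. The count of 1 over all times was reached by 4 of 61 splits (highest other 3), so chance cannot be excluded. At 8 h 7 of 10 splits, the real one included, gave at least 144 (highest other 160, median of the others 147). At 0 h in experiment 1 3 of 10 gave at least 118 (highest other 404). Although 10 splits are too few for a share under 0.05, neither real count stood out from the others. The high counts of other splits point to a structure of the samples, which single libraries would also give.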
